A study of Homo sapiens with 8 samples.

How the data were processed

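RNA of 8 samples was hybridised to 8 single-colour Affymetrix arrays after biotin labelling, per the labels. The samples fall into 4 groups of 2, EerI at 0 h, EerI at 10 h, Bzm at 0 h and Bzm at 10 h, as the labels' source entries give them. The values used are the authors' deposited intensity values, 1 per probe set and array, on a linear scale. They are MAS5 signals, per the submitters' processing notes. MAS5 subtracts mismatch-based background and scales each array to a common mean. The software version is not given in the sources used here. The deposited table holds 22277 probe sets, and its 8 arrays have 2% trimmed means that differ by at most 0.00608%, so no further scaling was applied. Such scaling hides a change in the total amount of messenger RNA. MAS5 values near background vary widely between arrays, which raises the spread of dim probe sets.

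From these values, log2 was taken with no offset. The 62 control probe sets were left out, and a probe set was kept if it lay above its array's own 40th percentile on at least 2 of the 8 arrays, which left 15016. Probe sets were named through the platform annotation, with symbols looked up by gene ID in a RefSeq table of human assembly GRCh38.p14, used for names only. Of the non-control probe sets 19064 carried 1 gene symbol, 1043 several and 2108 none, and the gene ID of 19052 of the first kind matched the RefSeq table. No gene was named from a probe set with several symbols. A gene is represented by the probe set with the highest mean log2 value that names this gene alone, which gave 8595 genes.

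One limma fit (version 3.58.1, R 4.3.3) used all 8 arrays with 4 group means, lmFit and eBayes with an intensity trend, and Benjamini-Hochberg adjustment over all probe sets kept. It has 4 residual degrees of freedom and 5.91 prior ones. Contrasts were 10 h minus 0 h for each compound, the difference of the 2 effects, and EerI 0 h minus Bzm 0 h. An adjusted p under 0.05 counts as a change. The 24 pathway lists and 7 cell type marker lists were fixed before the data were examined. The pathway lists cover the integrated stress response, ER chaperones, ER-associated degradation and p97, the proteasome, the immunoproteasome, heat shock, NRF2 targets, metallothioneins, the BCL2 family, death receptors and caspases, p53 targets, G1/S, G2/M, histones, Polycomb and H2A ubiquitination, deubiquitinases, NF-kB targets, immediate-early genes, cholesterol, ribosome biogenesis, autophagy, the respiratory chain, glycolysis and hypoxia, and B-cell identity. Lists were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 24 lists of a contrast. In the report, list calls hold with both settings unless a second p of 0.05 or more is given. The adjusted p printed first is that of the preset correlation, and that with an estimated correlation was larger. With EerI camera then gave an adjusted p of 0.00494 for the integrated stress response and 0.0464 for ER-associated degradation and NRF2 targets. For ER chaperones with Bzm it was 0.0437. List calls under alternatives were tested with the preset correlation alone. Genes named in the text are PMAIP1, the 10 largest rises and falls per compound among genes past the threshold with no overlap between the arrays of both times and the higher group mean above the median of all probe sets kept, the 5 largest differences on each side, and up to 4 members of each list by size of change. The text names part of these. Genes with a group mean below the 40th percentile of its arrays were left out or given as signals, a choice made after their values were seen. None of the genes named had another probe set that changed past the threshold in the opposite direction. Log2 changes of single genes in the report passed the adjusted p of their contrast, unless a failing p is given, and carry the standard error of the fit, while the closing list of differences between the effects gives none. As that fit has a common spread, errors and p-values of single genes tend to be too small for EerI and too large for Bzm. With arrays weighted by compound 13 of 215 single-gene results were lost.

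The scripts were tested on simulated data, 10 runs of 15016 probe sets with 200 changed per compound by 1.5, 2 or 4 times. With an equal spread in all arrays 5.32% of EerI calls and 5.44% of Bzm calls were false. With the spreads measured in each compound, the common-spread fit made 22.1% false EerI calls and 0% false Bzm calls. It recovered 45.2% of the 2-fold and 72.9% of the 4-fold EerI changes, and 40.9% and 70.3% of the Bzm ones. With limma's array weights by compound, 4.91% of EerI calls and 7.09% of Bzm calls were false. Shares of false calls depend on the share of probe sets changed, which was smaller here than the share called in the data. Probe sets of like signal were also given the same spread, so these shares do not carry over to the data. The weights were 0.516 for EerI and 1.94 for Bzm arrays. In the same runs a list of 25 probe sets shifted by 0.5 was called in 10 of 10 runs, and 0 of 230 unshifted lists were called. These lists were drawn with no correlation between members.

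Alternatives fixed before the data were examined were quantile normalization, centring on the median, an offset of 13.8 before the log, a floor at the 20th percentile, no filter, a filter at the 60th percentile, no intensity trend, a robust spread, only the compound's 4 arrays, the replicate number as a block, leaving out each array, averaging a gene's probe sets, and other thresholds. The weighting by compound was added after the data were seen. Limma was loaded with statmod 1.5.0. Figures were drawn with matplotlib 3.10.9. No sample was left out of the main fit.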

Results

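Gene expression was measured on 8 single-colour Affymetrix arrays of 22277 probe sets, in human cells that the series title calls cancer cells. The labels used here name no cell line and no dose. Cells received EerI or Bzm and were collected at 0 h or at 10 h, which gives 4 groups of 2 arrays each. EerI is the usual abbreviation of eeyarestatin I, an inhibitor of the degradation of misfolded proteins of the endoplasmic reticulum (ER) that acts through the ATPase p97. Bzm is that of bortezomib, an inhibitor of the proteasome. The series title asks how such inhibitors activate NOXA, a pro-apoptotic BH3-only protein encoded by PMAIP1. Each compound had its own 0 h arrays, so the 2 comparisons of 10 h with 0 h share no array. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. No untreated or vehicle-treated arrays at 10 h were analysed here, so time in culture and treatment cannot be told apart in either comparison. The number of arrays limits the precision of every value. One array, EerI 0 h replicate 2, is given as 0 h by its title, source and treatment entries and as 10 h by its description. It was kept at 0 h.

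Replicates of the EerI arrays differed more than those of the Bzm arrays. The median absolute log2 difference between the 2 replicates was 0.28 at 0 h and 0.30 at 10 h for EerI, against 0.14 and 0.16 for Bzm. The fit fixed before the data were examined gave all arrays 1 common spread. On simulated arrays with the measured spreads, this fit made 22.1% false calls among its EerI calls and 0% among its Bzm calls. Total counts are therefore also given from a fit that weights the arrays by compound, a choice made after the data were seen. In the same simulation its false calls were 4.91% for EerI and 7.09% for Bzm. These simulated shares do not carry over to the data. Member counts of lists come from the common spread unless another fit is named. They tend to favour EerI and are not to be compared between the compounds. With only each compound's own arrays, rises among ER chaperones went from 21 to 17 for EerI and from 8 to 12 for Bzm. Proteasome rises with Bzm went from 25 to 29, while integrated stress response rises with EerI stayed at 31. Other EerI counts shrank more. Rises went from 11 to 6 for heat shock and from 13 to 9 for both ER-associated degradation and autophagy. Proteasome counts with EerI went from 6 up and 8 down to 2 up and 5 down. Of the 7 cell type lists examined, the B-cell list had all 8 of its markers on the array above the filter. Of the other lists, 4 of 9 T or NK cell, 2 of 7 myeloid, 3 of 5 erythroid, 5 of 9 epithelial, 6 of 9 fibroblast and 3 of 9 neural markers passed it. Passing does not show expression, as dim probe sets pass too. The median over a list of each marker's highest mean signal was 1787 for B cells. It was 30.3, 21.5, 69.5, 33.0, 44.8 and 19.9 for the other lists in that order. The brightest marker outside the B-cell list was TUBB3, at 4879. Of the 8 B-cell markers 6 fell with EerI and 5 with Bzm, and none rose (7 and 8 fell adjusted over the list alone). In the other lists KRT18 rose from a mean signal of 19.7 to 191 (adjusted p = 0.00212) and CD7 fell from 82.8 to 22.0 (adjusted p = 0.0434) with EerI, the lower signal of each being below the 40th percentile of its arrays. SNAP25 rose by 1.04 (SE 0.23, adjusted p = 0.0092) and TUBB3 fell by 0.74 (SE 0.105, adjusted p = 0.000739) with EerI, and SNAP25 fell by 0.92 (SE 0.23, adjusted p = 0.0217) with Bzm. No marker of the myeloid, erythroid or fibroblast list changed past the limma threshold under EerI or Bzm.

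PMAIP1 rose under both compounds. After 10 h with EerI the signal of its brighter probe set was 5002 ± 548 against 1414 ± 102 at 0 h (SD, n = 2 each), a log2 change of 1.82 with a standard error of 0.10 (limma, adjusted p = 2.48e-06). With Bzm the signal was 6111 ± 104 against 3254 ± 170, a log2 change of 0.91 with a standard error of 0.10 (limma, adjusted p = 0.000241). The equal standard errors come from the common spread. With arrays weighted by compound the adjusted p of limma was 5.02e-06 for EerI and 1.15e-06 for Bzm. Both 10 h arrays lay above both 0 h arrays in each comparison, and the other probe set of the gene changed in the same direction past the threshold. The rise was larger under EerI by 0.91 on the log2 scale (SE 0.14, limma, adjusted p = 0.00489). The starting signals differed too, and the 0 h groups carry different dates in their labels, so the larger rise began from a lower signal. The highest signal of a probe set was 27809 on the Bzm arrays and 113102 on the EerI arrays. Over probe sets with a log2 signal above 13 on the Bzm 0 h arrays the median absolute log2 change was 0.16 with Bzm and 0.30 with EerI. It was 0.25 and 0.37 between 12 and 13, and 0.29 and 0.33 between 10 and 12. Between 8 and 10 it was 0.30 and 0.34, and under 8 it was 0.38 and 0.59. The EerI value was thus larger among dim probe sets too. This difference in range was not removed from the differences between the effects, those of PMAIP1 and other bright genes included.

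**Figure D1:**
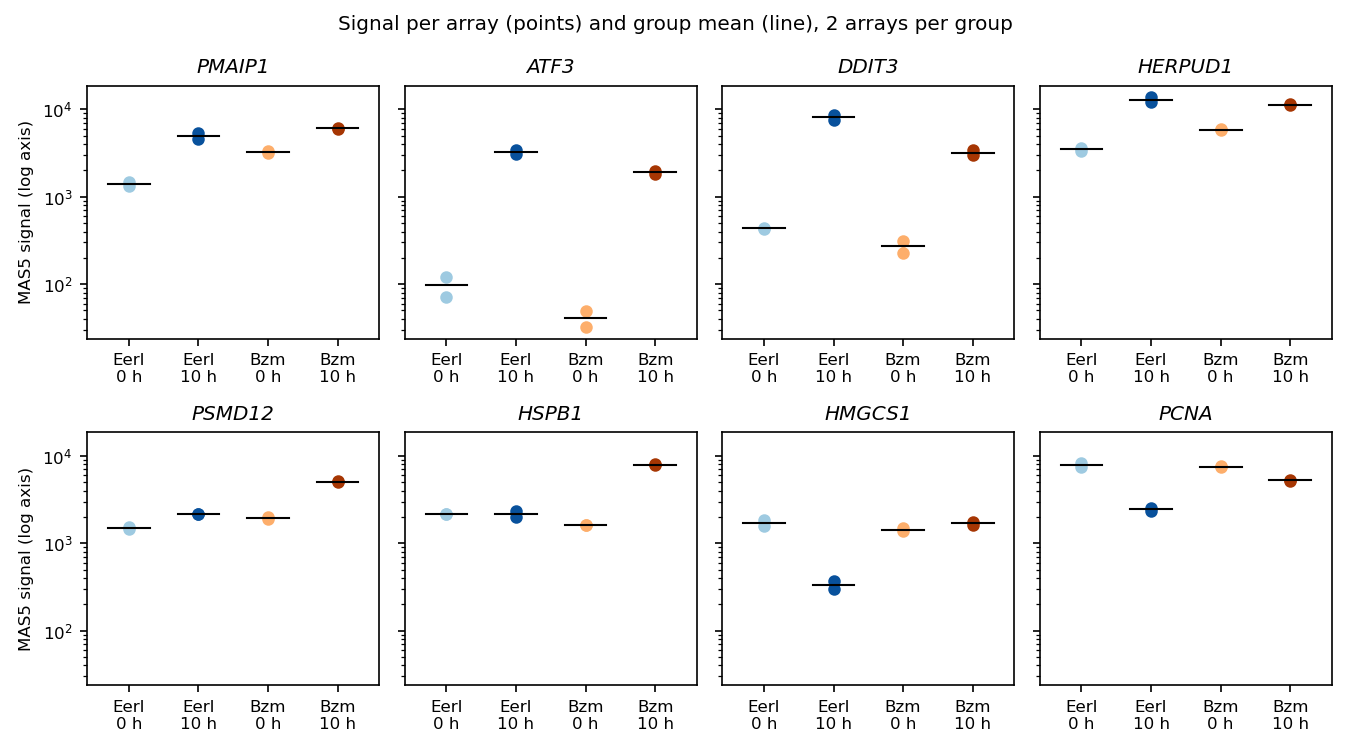
MAS5 signal on a log axis for 8 named genes, with 1 point per array (blue for EerI, orange for Bzm, darker at 10 h) and a line at the mean of each group of 2 arrays. PMAIP1 goes from a mean of 1414 to 5002 under EerI and from 3254 to 6111 under Bzm, PSMD12 from 1931 to 5043 under Bzm, and HMGCS1 from 1713 to 335 under EerI.

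The first comparison asks what differed between 10 h and 0 h of EerI. Targets of the integrated stress response, the ATF4 and CHOP programme, rose together. Of 35 measured genes 31 rose, 0 fell and 4 did not pass (32 and 0 adjusted over the list alone), with a median log2 change of 1.70 (camera, adjusted p = 1.83e-27). The stress transcription factor ATF3 rose by 5.11 (SE 0.27), the pseudokinase TRIB3 by 4.71 (SE 0.11) and DDIT3, which encodes CHOP, by 4.21 (SE 0.15). CHAC1, a glutathione-degrading enzyme, rose by 4.76 (SE 0.81) from a 0 h signal of 82.0 ± 96.0 (SD, n = 2). Without EerI 0 h replicate 1 this rise was 6.46, and without EerI 0 h replicate 2 it was 3.06. Of 31 ER chaperones and folding enzymes 21 rose, 0 fell and 10 did not pass (23 and 1 adjusted over the list alone; camera, adjusted p = 5.04e-10). DNAJB9, a co-chaperone of the ER, rose by 2.33 (SE 0.14), and HSPA5, the ER chaperone BiP, by 1.17 (SE 0.09). Of 28 genes of ER-associated degradation and p97 13 rose, 1 fell and 14 did not pass (13 and 1 adjusted over the list alone; camera, adjusted p = 0.00171). SEL1L, part of the ubiquitin ligase complex of this pathway, rose by 2.00 (SE 0.14) and HERPUD1 by 1.89 (SE 0.08).

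Genes of the oxidative stress response under NRF2 also rose with EerI, 13 of 26, while 2 fell and 11 did not pass (13 and 2 adjusted over the list alone; camera, adjusted p = 0.000721). HMOX1, the haem oxygenase, rose by 3.44 (SE 0.21) and the autophagy receptor SQSTM1 by 1.70 (SE 0.17). Of 22 heat shock genes 11 rose, 1 fell and 10 did not pass (11 and 1 adjusted over the list alone; camera, adjusted p = 0.0157), a call that is lost with an estimated correlation (adjusted p = 0.094) and with arrays centred on their median (7 and 3 genes, adjusted p = 0.0936). SERPINH1, a collagen chaperone, rose by 2.10 (SE 0.28) and the co-chaperone BAG3 by 1.34 (SE 0.18). Of 26 autophagy and lysosome genes 13 rose, 1 fell and 12 did not pass (14 and 1 adjusted over the list alone; camera, adjusted p = 0.00012, adjusted p = 0.11 with an estimated correlation). MAP1LC3B, which coats autophagosomes, rose by 1.77 (SE 0.13). Of 39 deubiquitinases 8 rose, 2 fell and 29 did not pass (8 and 2 adjusted over the list alone; camera, adjusted p = 0.042, adjusted p = 0.349 with an estimated correlation). CYLD, known as a brake on NF-kB signalling, rose by 1.19 (SE 0.22). The call of the deubiquitinases, with a median of 0.21, was also lost with arrays centred (adjusted p = 0.1), with the filter at the 60th percentile, without the intensity trend and with probe sets averaged per gene. It was lost without EerI 10 h replicate 1 (median 0.15) and without EerI 0 h replicate 1 (0.24).

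Cholesterol synthesis genes fell with EerI. Of 18 measured genes 0 rose, 13 fell and 5 did not pass (0 and 15 adjusted over the list alone), with a median log2 change of -1.13 (camera, adjusted p = 1.44e-11). The methylsterol oxidase gene MSMO1 fell by 2.38 (SE 0.10), HMGCS1, which makes HMG-CoA, fell by 2.36 (SE 0.14) and SQLE, the squalene epoxidase, fell by 1.71 (SE 0.11). Of 38 G1/S and DNA replication genes 0 rose, 30 fell and 8 did not pass (0 and 31 adjusted over the list alone; camera, adjusted p = 3.67e-18). The ribonucleotide reductase subunit RRM2 fell by 2.08 (SE 0.12) and the sliding clamp PCNA fell by 1.70 (SE 0.08). Of 39 G2/M and mitosis genes 0 rose, 18 fell and 21 did not pass (1 and 21 adjusted over the list alone; camera, adjusted p = 9.63e-07). PTTG1, the securin gene, fell by 1.03 (SE 0.08) and CDK1 fell by 0.85 (SE 0.14). Of 29 nuclear-coded respiratory chain genes 0 rose, 21 fell and 8 did not pass (0 and 23 adjusted over the list alone; camera, adjusted p = 1.44e-11), and COX7B fell by 1.32 (SE 0.10). Of 25 glycolysis and hypoxia genes 1 rose, 10 fell and 14 did not pass (2 and 10 adjusted over the list alone; camera, adjusted p = 0.00093). The lactate dehydrogenase gene LDHA fell by 1.02 (SE 0.07) and the phosphofructokinase gene PFKP fell by 0.96 (SE 0.13). Of 25 genes of B-cell receptor signalling and identity 2 rose, 16 fell and 7 did not pass (2 and 18 adjusted over the list alone; camera, adjusted p = 6.19e-07). The transcription factor SPIB fell by 2.03 (SE 0.08), whereas IRF4 rose by 1.90 (SE 0.09). With an estimated correlation the camera adjusted p was 0.0449 for G2/M and 0.0464 for the respiratory chain, glycolysis and B-cell identity.

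The proteasome list was not called with EerI, with 6 of 37 genes rising, 8 falling and 23 not passing (7 and 8 adjusted over the list alone; camera, adjusted p = 0.641). This split depends on the scaling. With arrays centred on their median 1 rose and 9 fell, the median log2 change of 0.01 becoming -0.13, and with quantile normalization 7 rose and 5 fell, with a median of 0.08. SEM1 fell by 1.20 (SE 0.09) and the catalytic subunit PSMB5 fell by 0.58 (SE 0.10). Calls were not made either for the immunoproteasome (5 up, 5 down of 13), metallothionein (2 up, 0 down of 8), death receptor and caspase (4 up, 3 down of 18), p53 target (2 up, 1 down of 18), histone (3 up, 3 down of 14), Polycomb (3 up, 1 down of 22) or ribosome biogenesis lists (4 up, 3 down of 23), with camera adjusted p from 0.124 to 0.872. These counts were the same adjusted over the list alone, except for 6 down in the immunoproteasome list and 4 down in the death receptor list. The immunoproteasome list had 0 up and 6 down with arrays centred and 0 up and 3 down with arrays weighted by compound, and the ribosome biogenesis list 1 up and 4 down with arrays centred. Camera put the proteasome, immunoproteasome and ribosome biogenesis lists lower although their medians were 0.01, 0.11 and 0.06, which became -0.13, -0.03 and -0.08 with arrays centred. Outside the lists, the signal of INHBE, a secreted factor, rose from 37.8 ± 27.3 to 1453 ± 224 (SD, n = 2 each). The 0 h mean lay below the 40th percentile of both arrays, 69.7 and 73.4, so no fold is given. ID3, an inhibitor of helix-loop-helix transcription factors, fell by 3.81 (SE 0.15). The lymphocyte surface protein gene CD52 fell by 2.73 (SE 0.15).

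In all, 3709 of 15016 probe sets changed with EerI in the limma fit at an adjusted p under 0.05, 2064 higher and 1645 lower. With arrays weighted by compound the count was 2064, with 1078 higher and 986 lower, and with only the 4 EerI arrays it was 2092, with 1075 higher and 1017 lower. Without the intensity trend it was 2441. Centring each array on its median, which lowers every EerI log2 change by about 0.14, gave 1389 higher and 2226 lower. Control probe sets, which were not tested, moved on the same arrays. That for the 3' end of 18S ribosomal RNA had a mean signal of 1934 at 0 h and 5396 at 10 h, and the 3' beta-actin control had 59838 and 19884.

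The comparison of Bzm at 10 h with 0 h asks the same of a proteasome inhibitor. Integrated stress response targets rose in 32 of 35 cases, 0 fell and 3 did not pass (32 and 0 adjusted over the list alone), with a median log2 change of 1.42 (camera, adjusted p = 3.45e-36). TRIB3 rose by 4.36 (SE 0.11), SLC7A11, the cystine transporter, by 3.74 (SE 0.15) and DDIT3 by 3.58 (SE 0.15). The signal of ATF3 rose from 40.6 ± 11.8, about the 40th percentile of the Bzm arrays, to 1895 ± 83.4 (SD, n = 2 each). Of 37 proteasome genes 25 rose, 0 fell and 12 did not pass (28 and 0 adjusted over the list alone), with a median of 0.62 (camera, adjusted p = 2.83e-20). The regulatory particle subunits PSMD12, PSMD11 and PSMD14 rose by 1.39 (SE 0.08), 1.23 (SE 0.10) and 1.20 (SE 0.08). Of 22 heat shock genes 20 rose, 0 fell and 2 did not pass (21 and 0 adjusted over the list alone; camera, adjusted p = 2.97e-21). BAG3 rose by 3.12 (SE 0.18), HSPA6, an inducible HSP70, by 2.74 (SE 0.40) and the small heat shock protein gene HSPB1 by 2.29 (SE 0.09).

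Of 26 NRF2 targets 16 rose with Bzm, 1 fell and 9 did not pass (18 and 1 adjusted over the list alone; camera, adjusted p = 3.39e-09), and MAFG, which encodes a partner of NRF2, rose by 1.75 (SE 0.14). Of 28 genes of ER-associated degradation and p97 14 rose, 1 fell and 13 did not pass (15 and 2 adjusted over the list alone; camera, adjusted p = 6.29e-06). NPLOC4, a p97 cofactor, rose by 1.52 (SE 0.14) and SEL1L by 1.29 (SE 0.14). Of 31 ER chaperones 8 rose, 2 fell and 21 did not pass (10 and 2 adjusted over the list alone; camera, adjusted p = 0.000506). HSPA5 rose by 0.89 (SE 0.09) and DNAJB9 by 0.75 (SE 0.14). Deubiquitinases rose in 7 of 39 cases, 3 fell and 29 did not pass (9 and 3 adjusted over the list alone; camera, adjusted p = 0.00872, adjusted p = 0.243 with an estimated correlation). UCHL1 rose by 1.64 (SE 0.15). Autophagy genes rose in 6 of 26 cases, 1 fell and 19 did not pass (8 and 1 adjusted over the list alone; camera, adjusted p = 0.0394, adjusted p = 0.317 with an estimated correlation). SQSTM1 rose by 1.54 (SE 0.17). The autophagy call was also lost with probe sets averaged per gene (adjusted p = 0.102) and without Bzm 10 h replicate 2, where the median was 0.11.

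Genes of G2/M and mitosis fell with Bzm, 21 of 39, while 1 rose and 17 did not pass (1 and 26 adjusted over the list alone; camera, adjusted p = 4.57e-09). PLK1, a mitotic kinase, fell by 0.89 (SE 0.12). Of 38 G1/S genes 0 rose, 10 fell and 28 did not pass (0 and 11 adjusted over the list alone; camera, adjusted p = 0.0144, adjusted p = 0.106 with an estimated correlation, adjusted p = 0.0559 with the filter at the 60th percentile). The thymidine kinase gene TK1 fell by 1.18 (SE 0.16). Of 29 respiratory chain genes 0 rose, 13 fell and 16 did not pass (0 and 17 adjusted over the list alone; camera, adjusted p = 5.84e-07, adjusted p = 0.0917 with an estimated correlation), COX7B among them, which fell by 1.16 (SE 0.10). Of 8 metallothionein and zinc response genes 0 rose, 6 fell and 2 did not pass (0 and 6 adjusted over the list alone; camera, adjusted p = 0.000571, adjusted p = 0.0911 with an estimated correlation), and MT2A fell by 1.18 (SE 0.15). Of 25 B-cell identity genes 2 rose, 9 fell and 14 did not pass (2 and 11 adjusted over the list alone; camera, adjusted p = 0.000876, adjusted p = 0.108 with an estimated correlation), and CD79A, part of the B-cell receptor, fell by 0.95 (SE 0.08).

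Cholesterol genes had no common direction with Bzm, 2 rising, 4 falling and 12 of 18 not passing (2 and 6 adjusted over the list alone; camera, adjusted p = 0.499). Calls were not made for the immunoproteasome (3 up, 4 down of 13), death receptor and caspase (2 up, 2 down of 18), p53 target (3 up, 4 down of 18), histone (1 up, 3 down of 14), Polycomb (2 up, 2 down of 22), glycolysis (0 up, 6 down of 25) or ribosome biogenesis lists (0 up, 3 down of 23), with camera adjusted p from 0.118 to 0.879. Adjusted over the list alone, the immunoproteasome list had 4 up and the Polycomb list 5 up, and the other counts were the same. Camera put the glycolysis list lower although its median was 0.01. CDKN1A, the cell cycle inhibitor p21, rose by 1.30 (SE 0.15). Among single genes, the transcription factor JUN rose by 3.48 (SE 0.31). The signal of INHBE rose from 10.8 ± 4.31, below the 40th percentile of those arrays, to 592 ± 22.8 (SD, n = 2 each). CD52 fell by 2.81 (SE 0.15) and GPER1, a G protein-coupled oestrogen receptor gene, fell by 2.75 (SE 0.12).

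In the same limma fit 2418 of 15016 probe sets changed with Bzm, 1064 higher and 1354 lower. Centring each array on its median gave 1206 higher and 1138 lower. With arrays weighted by compound the count was 5004, with 2258 higher and 2746 lower, and with only the 4 Bzm arrays it was 4720, with 2143 higher and 2577 lower. Without the intensity trend it was 1329. The order of the EerI and Bzm counts therefore turned with the treatment of the spread, and the counts do not rank the compounds. Leaving out 1 of the Bzm arrays left between 1022 and 1242 probe sets.

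**Figure D2:**
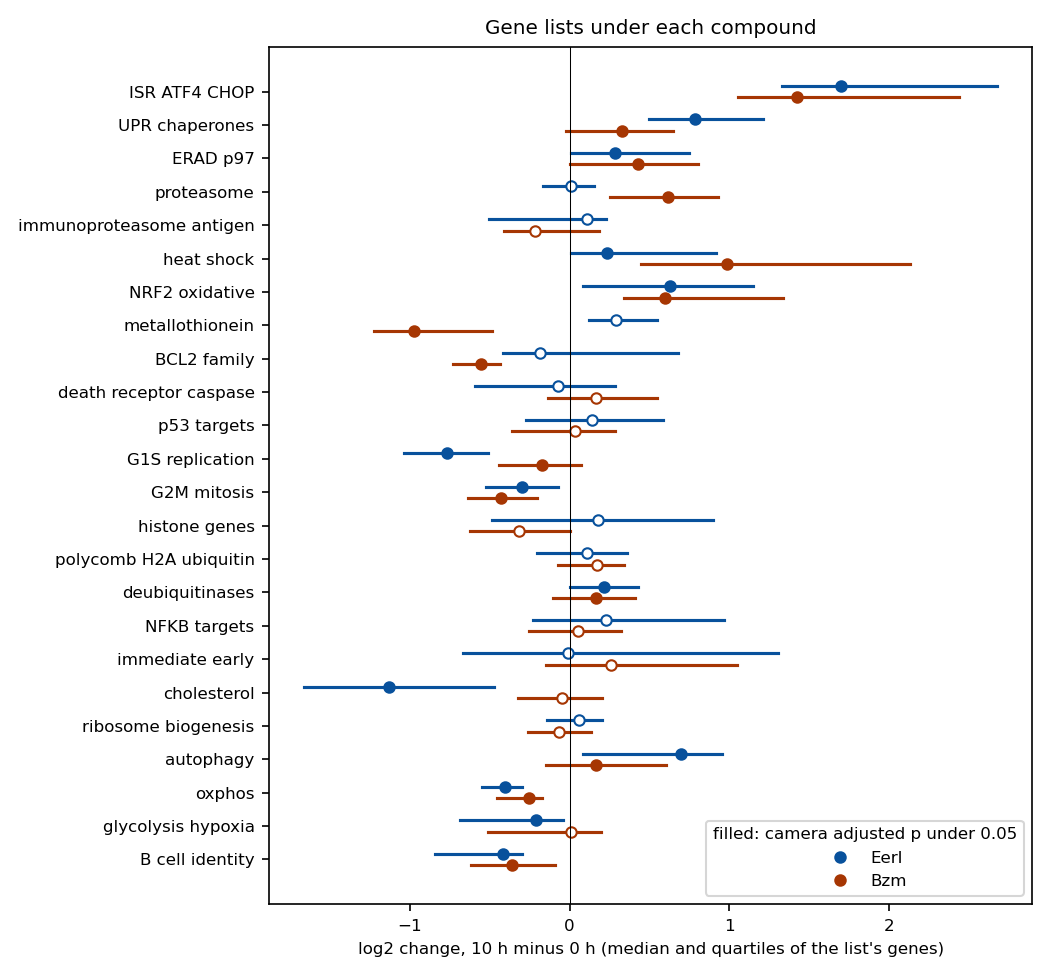
Median (point) and quartiles (line) of the log2 change at 10 h over the genes of each of the 24 lists, for EerI (blue) and Bzm (brown), with filled points where camera gave an adjusted p under 0.05. The proteasome list has a median of 0.62 under Bzm and 0.01 under EerI, which becomes -0.13 with arrays centred, and the cholesterol list -1.13 under EerI and -0.04 under Bzm.

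The next comparison asks where the 2 compounds differed, by the interaction in the limma fit. A gene is called lower under EerI here where its EerI effect was more negative than its Bzm effect, and higher where it was more positive. Proteasome genes were lower under EerI in 25 of 37 cases and higher in 0, while 12 did not pass (30 and 1 adjusted over the list alone; camera, adjusted p = 1.81e-24). PSMD12 differed by -0.87 (SE 0.12, adjusted p = 0.00287), less than its rise with Bzm, so that its log2 change with EerI was also positive. Heat shock genes were lower under EerI in 10 of 22 cases and higher in 0, while 12 did not pass (15 and 0 adjusted over the list alone; camera, adjusted p = 1.44e-15), and HSPB1 differed by -2.28 (SE 0.13). Cholesterol genes were lower under EerI in 10 of 18 cases and higher in 0, while 8 did not pass (11 and 1 adjusted over the list alone; camera, adjusted p = 9.2e-12). MSMO1 differed by -2.91 (SE 0.15) and HMGCS1 by -2.60 (SE 0.19). G1/S genes were lower under EerI in 15 of 38 cases and higher in 0, while 23 did not pass (22 and 0 adjusted over the list alone; camera, adjusted p = 5.98e-16), and PCNA differed by -1.18 (SE 0.12). ER chaperones were higher under EerI in 7 of 31 cases and lower in 0, while 24 did not pass (8 and 0 adjusted over the list alone; camera, adjusted p = 5.58e-06), and DNAJB9 differed by 1.58 (SE 0.20).

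Metallothionein genes were higher under EerI in 6 of 8 cases and lower in 0, while 2 did not pass (7 and 0 adjusted over the list alone; camera, adjusted p = 6.66e-06, adjusted p = 0.053 with an estimated correlation), and MT2A differed by 1.84 (SE 0.21). With quantile normalization 3 metallothionein genes were higher, and with arrays centred 4 were. The BCL2 family was higher under EerI in 4 of 15 cases and lower in 0, while 11 did not pass (5 and 1 adjusted over the list alone; camera, adjusted p = 0.00762, adjusted p = 0.1 with an estimated correlation). Glycolysis genes were lower under EerI in 5 of 25 cases and higher in 1, while 19 did not pass (7 and 1 adjusted over the list alone; camera, adjusted p = 0.000939, adjusted p = 0.053 with an estimated correlation). The respiratory chain (0 up, 1 down of 29, and 0 and 0 adjusted over the list alone, camera, adjusted p = 0.00403) and B-cell identity lists (1 up, 1 down of 25, and 2 and 4 adjusted over the list alone, camera, adjusted p = 0.0242) were called lower. The autophagy list (3 up, 0 down of 26, and 8 and 1 adjusted over the list alone, camera, adjusted p = 0.0252) was called higher. With an estimated correlation these 3 calls were lost, at adjusted p = 0.274, adjusted p = 0.267 and adjusted p = 0.299. The respiratory chain difference turned from a median of -0.15 to 0.11 with quantile normalization, which also ended the B-cell identity call (adjusted p = 0.394). That call was lost without EerI 10 h replicate 1 (median -0.17) and without EerI 0 h replicate 2 (-0.25), and the autophagy call without EerI 0 h replicate 2 (0.38) and without EerI 10 h replicate 2 (0.36). The autophagy call was also lost without the intensity trend (adjusted p = 0.0544) and with probe sets averaged per gene (adjusted p = 0.132). With arrays centred the B-cell identity list had 1 up and 7 down, the respiratory chain list 0 up and 5 down and the autophagy list 2 up and 1 down. Integrated stress response targets differed in 5 genes upward and 1 downward of 35 (5 and 3 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.0703). With arrays centred these counts were 2 and 3. Among single genes, the phosphodiesterase gene PDE9A differed by 3.69 (SE 0.32), ID3 by -2.58 (SE 0.21) and TMEM100 by -2.40 (SE 0.15).

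In all, 975 of 15016 probe sets differed between the effects, 550 more positive under EerI and 425 more negative. With arrays weighted by compound 900 differed, and without the intensity trend 179 did, 108 more positive and 71 more negative. In the simulation 2.59% of the calls of the common-spread fit were false for this contrast, a share that does not carry over to the data. Centring arrays on their median, which lowers every difference by about 0.19, gave 317 and 780. Leaving out 1 of the Bzm arrays left between 348 and 406.

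Across 8595 genes the changes under EerI and Bzm correlated with a Pearson r of 0.33 and a Spearman rank coefficient of 0.35, a description across genes, which are not independent replicates. With the filter at the 60th percentile r was 0.54. Over the 4683 genes above the median signal r was 0.59. Of the genes, 390 rose under both compounds, against 97.3 for independent lists, and 445 fell under both, against 111 for independent lists. These 835 shared calls became 440 without the intensity trend, and 468, 507, 432 and 438 without Bzm 0 h replicate 1, Bzm 10 h replicate 1, Bzm 0 h replicate 2 and Bzm 10 h replicate 2. Time in culture is common to both comparisons. Another 63 went in opposite directions, against 216 for independent lists. Fisher's exact test as a description gave p = 3.23e-171 for the shared rises and p = 1.74e-193 for the shared falls. TRIB3, DDIT3 and SLC7A11, whose signals lay above the 40th percentile in every group, rose under both.

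**Figure D3:**
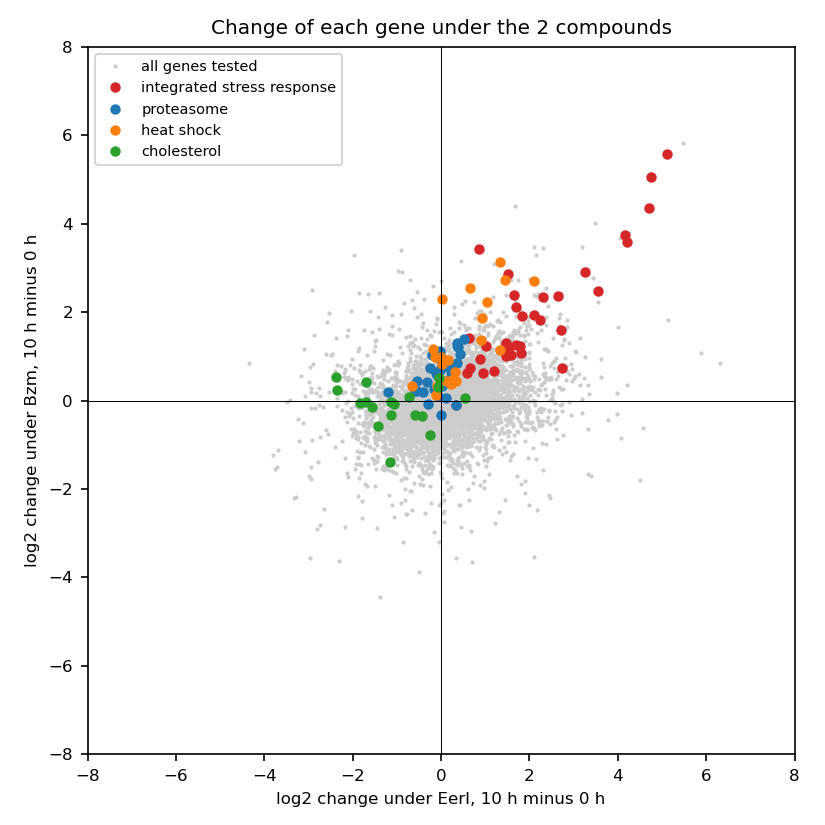
Log2 change at 10 h under EerI (x axis) and under Bzm (y axis), 1 point per gene (grey), with the integrated stress response (red), proteasome (blue), heat shock (orange) and cholesterol (green) lists in colour. Integrated stress response genes lie high on both axes, with medians of 1.70 and 1.42, while proteasome and heat shock genes lie higher on the Bzm axis and cholesterol genes lower on the EerI axis.

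The 0 h arrays of EerI and Bzm were compared as a description only. Between them 4973 of 15016 probe sets differed in the limma fit, 2595 higher on the EerI arrays and 2378 lower. Without Bzm 0 h replicate 1 the count was 2548 and without Bzm 0 h replicate 2 it was 2625. The labels give each compound's arrays a date of their own, so that compound and date cannot be told apart here. Probe sets with a log2 signal over 13 on the Bzm 0 h arrays were higher on the EerI 0 h arrays by a median of 0.95.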

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

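The tests of scaling, RNA degradation, array spread and messenger RNA amount given here were chosen only after the results were seen, while both tests on the actin-binding genes were written down before their values were looked at. The effects of EerI and Bzm differed in 975 probe sets by the interaction test in limma. Of the genes named in the text 35 passed this test, 14 with a more positive EerI effect and 21 with a more negative one. Each gene is given by 1 representative probe set. For BCL2 the rise with EerI was lost with probe sets averaged per gene. The differences, EerI minus Bzm on the log2 scale, were 3.69 for PDE9A, 2.81 for GPER1, 2.53 for HRK, 2.05 for BCL2, 1.96 for SNAP25, 1.84 for MT2A, 1.74 for MYC, 1.65 for NFKBIE, 1.58 for DNAJB9, 1.24 for RELB, 1.14 for IRF4, 0.95 for H2AC6, 0.95 for HERPUD1 and 0.91 for PMAIP1. On the other side the differences were -2.91 for MSMO1, -2.60 for HMGCS1, -2.58 for ID3, -2.40 for TMEM100, -2.28 for HSPB1, -1.88 for KLF2, -1.78 for BAG3, -1.72 for RRM2, -1.67 for SQLE, -1.40 for SEM1, -1.40 for SPIB, -1.30 for NPLOC4, -1.19 for CDKN1A, -1.18 for PCNA, -1.01 for UCHL1, -0.87 for PSMD11, -0.87 for PSMD12, -0.81 for PSMD14, -0.79 for PSMB5, -0.62 for LDHA and -0.61 for TUBB3. Of the lists 11 differed by camera with the preset correlation. The median differences of the 5 that also pass with an estimated correlation were 0.48 for ER chaperones, -0.82 for cholesterol, -0.77 for heat shock, -0.69 for the proteasome and -0.57 for G1/S. The other 6 fail with it, with medians of 1.14 for metallothioneins (adjusted p = 0.053), 0.59 for the BCL2 family (adjusted p = 0.1), 0.47 for autophagy (adjusted p = 0.299), -0.37 for glycolysis (adjusted p = 0.053), -0.29 for B-cell identity (adjusted p = 0.267) and -0.15 for the respiratory chain (adjusted p = 0.274). With arrays centred the medians became 0.29 for ER chaperones, 0.28 for autophagy, -0.55 for glycolysis, -0.48 for B-cell identity and -0.34 for the respiratory chain. With quantile normalization they became 0.29 for the BCL2 family and 0.11 for the respiratory chain.

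The first pattern is that the proteasome list was called higher with Bzm and not with EerI. With Bzm the mean of the list was higher on any 10 h array than on any 0 h array, by 0.57 to 0.63. The 4 EerI differences between such arrays ran from -0.056 to -0.000591. On these arrays the spread of the list mean thus hid no EerI rise of the size seen with Bzm. These differences share arrays, and they use the genes and arrays that gave the pattern. They are therefore no separate test of the larger spread of the EerI arrays as the cause, which stays open. Scaling between arrays is argued against by the difference over the list relative to all genes, -0.65 with quantile normalization. A difference between what the compounds do to these genes may remain, as a hypothesis, but each compound was run on its own date and the dose is not in the labels, so that a difference in date or dose stays open, untested.

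The next pattern is that the 3' beta-actin control was lower at 10 h with EerI, by a log2 change of -1.59. Partial RNA degradation would raise the ratio of 3' to 5' actin signal, which was higher by 0.16 on the log2 scale at 10 h, with at most 0.32 on any array. If actin cytoskeleton genes were expressed at a lower level after EerI, other actin-binding genes should be lower too. Of 33 measured ones 4 rose, 13 fell and 16 did not pass with EerI, with a median of -0.40 (camera, p = 0.000118, p = 0.0115 with an estimated correlation) against -0.06 with Bzm (camera, p = 0.535), which is consistent with that hypothesis. Compression of bright signals on the Bzm arrays cannot lower an EerI signal and bears only on the smaller change with Bzm. The 27 dimmer actin-binding genes argue against it for themselves, their effects differing by a median of -0.35 relative to all genes. They cannot test it for the bright actin control, whose mean signal on the Bzm 0 h arrays was 17847.

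Some control probe sets, which were not tested, were higher on both 10 h arrays than on both 0 h arrays. With EerI the log2 differences were 1.48, 1.07 and 1.04 for the 3', 5' and middle probe sets of 18S ribosomal RNA, 1.22 and 0.45 for the 5' and middle probe sets of 28S ribosomal RNA, 0.36 for Alu, and 0.38, 0.44, 0.36 and 0.45 for the spike-in controls BioB, BioC, BioDn and CreX. With Bzm they were 0.36 for the middle 28S probe set and 0.15 for Alu. The 3' 18S probe set had a mean signal of 106 on the Bzm 0 h arrays, whose median signals were 95.6 and 91.4. On the EerI 0 h arrays its mean was 1934. The spike-in BioB had 939 on the Bzm and 6398 on the EerI 0 h arrays. The control changes can therefore not be compared between the compounds. Scaling of the EerI 10 h arrays would move ribosomal and spike-in probe sets alike, yet the median difference of the ribosomal ones was larger by 0.67. Less messenger RNA in the labelled EerI 10 h samples could raise both, and the spike-ins had a median difference of 0.41, but labels give no RNA amounts and the explanation cannot be told apart from a change in spike-in amount. No biological explanation was tested for this pattern.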

How the results depend on the processing

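Weighting the arrays by compound was chosen only after the data were seen, and the other alternatives were fixed earlier. PMAIP1 kept its direction and its side of the threshold under all 20 alternatives, with log2 changes from 1.68 to 2.05 for EerI and from 0.86 to 1.17 for Bzm. Of 215 results for single genes 150 were never lost where they had a value, 65 were lost under at least 1 alternative, and none changed direction. With the filter at the 60th percentile only 208 of them had a value. These genes were chosen by the size of their change in the same data, so their stability is partly built in. Of 38 list calls 30 were never lost under these alternatives, all tested with the preset correlation, but 16 of the 38 fail with an estimated correlation and 22 pass on both counts. The count for EerI was 1238 with a 2-fold minimum, 1957 at an adjusted p under 0.01, 1148 by a 2-fold change in both numbered pairs with no test, 2441 without the intensity trend, 2238 with probe sets averaged per gene, which tests fewer units, 2092 with only its own arrays and 2064 with weights. For Bzm these counts were 655, 1270, 787, 1329, 1608, 4720 and 5004. The last 2 fits give each compound its own spread, which moved the counts in opposite directions, and the smaller Bzm count of the common spread goes with the larger spread of the EerI arrays. The difference between the effects had 179 probe sets without the trend, and the shared calls numbered 440 there against 835. The comparison of the 0 h arrays had 2812 with probe sets averaged.

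The correlation of both effects was 0.404 with an offset, 0.368 with a floor and 0.541 with the filter at the 60th percentile. With quantile normalization the difference between the compounds turned to 0.11 (adjusted p = 0.235) for the respiratory chain list, was 0.43 for histones (adjusted p = 0.0232), now called, and -0.23 for B-cell identity (adjusted p = 0.394), no longer called. Centring ended the EerI calls of heat shock at 0.10 (adjusted p = 0.0936) and deubiquitinases at 0.075 (adjusted p = 0.1). With the offset the stress response difference of 0.33 was called (adjusted p = 0.0474). The filter at the 60th percentile ended the calls of deubiquitinases with EerI at 0.21 (adjusted p = 0.0548) and G1/S with Bzm at -0.17 (adjusted p = 0.0559), and NF-kB targets were called with EerI at 0.42 (adjusted p = 0.00856) and in the difference at 0.40 (adjusted p = 0.0255). Without the trend the calls of deubiquitinases with EerI at 0.21 (adjusted p = 0.0933) and of autophagy in the difference at 0.47 (adjusted p = 0.0544) were lost. With only the EerI arrays NF-kB targets were called at 0.23 (adjusted p = 0.0389). Averaging probe sets ended the calls of deubiquitinases with EerI at 0.15 (adjusted p = 0.115), of the BCL2 family with Bzm at -0.48 (adjusted p = 0.102), of autophagy with Bzm at 0.16 (adjusted p = 0.102) and of autophagy in the difference at 0.37 (adjusted p = 0.132), while histones were called in the difference at 0.34 (adjusted p = 0.0463). The cause was not tested in these cases.

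Leaving out 1 array leaves a group with a lone array, assumed to vary like the other groups. The counts then ranged from 2922 to 3639 for EerI, from 1022 to 2975 for Bzm, from 348 to 1358 for the difference and from 2548 to 5847 for the 0 h arrays, the correlation from 0.289 to 0.340 and the shared calls from 432 to 892. Without Bzm 0 h replicate 1, Bzm 10 h replicate 1, Bzm 0 h replicate 2 and Bzm 10 h replicate 2 the Bzm count was 1083, 1242, 1022 and 1067, and the difference lay between 348 and 406. List medians ranged from 0.11 to 0.26 for autophagy with Bzm, whose call was lost without Bzm 10 h replicate 2 (0.11). They ranged from 0.36 to 0.56 for autophagy in the difference, lost without EerI 0 h replicate 2 (0.38) or EerI 10 h replicate 2 (0.36). For B-cell identity in the difference the range was -0.29 to -0.17, the call being lost without EerI 10 h replicate 1 (-0.17) or EerI 0 h replicate 2 (-0.25). For deubiquitinases with EerI it was 0.15 to 0.28, lost without EerI 10 h replicate 1 (0.15) or EerI 0 h replicate 1 (0.24). Histones in the difference had 0.22 to 0.51 and were called without Bzm 10 h replicate 1 (0.50) or EerI 0 h replicate 1 (0.46). Without EerI 0 h replicate 2, the array with conflicting labels, 3187 probe sets changed with EerI. A fit with the replicate number as a replicate block gave 3418 probe sets for EerI, 2132 for Bzm, 651 for the difference and 750 shared calls, and changed no list call. Across probe sets the deviations of arrays with the same number correlated at -0.02 in EerI and -0.02 in Bzm, over 2 pairs each. No pairing was seen by this measure, which cannot show whether such arrays came from the same culture. The difference and the 0 h comparison cannot be given with only 1 compound's arrays, nor the 0 h comparison with the block. Dim probe sets near background limit all counts.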

Other observations

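The genes of the BCL2 family, which set the threshold of mitochondrial apoptosis, split in ways that the change of PMAIP1 alone does not show. With EerI 4 of 15 rose, 3 fell and 8 did not pass (4 and 3 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.815), with a median of -0.19 although camera put it higher. The BH3-only gene HRK rose by 1.89 (SE 0.26) and the anti-apoptotic BCL2 by 1.35 (SE 0.14). With Bzm 1 rose, 5 fell and 9 did not pass (1 and 6 adjusted over the list alone; camera, adjusted p = 0.00671, adjusted p = 0.0911 with an estimated correlation, adjusted p = 0.102 with probe sets averaged per gene). PMAIP1 was the gene that rose, while BID fell by 0.76 (SE 0.11) and BCL2 fell by 0.70 (SE 0.14). The probe set that represents BCL2 thus moved in opposite directions, by 2.05 (SE 0.20, limma, adjusted p = 0.000502) between the compounds. HRK differed by 2.53 (SE 0.37, limma, adjusted p = 0.00368). The 3 other BCL2 probe sets that passed the filter did not change past the threshold with EerI, and the EerI call was lost with probe sets averaged per gene (limma, adjusted p = 0.0917). The death receptor gene TNFRSF10B rose under both, by 0.89 (SE 0.17) and 1.07 (SE 0.17).

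Neither NF-kB targets nor immediate-early genes were called as lists in the difference between the compounds. NF-kB targets differed upward in 4 of 22 genes and downward in 0 (4 and 0 adjusted over the list alone; camera, adjusted p = 0.0846), and immediate-early genes upward in 1 of 19 and downward in 2 (1 and 4 adjusted over the list alone; camera, adjusted p = 0.5). Of 22 NF-kB targets 6 rose with EerI, 0 fell and 16 did not pass (6 and 0 adjusted over the list alone; camera, adjusted p = 0.0652), and with Bzm 2 rose, 1 fell and 19 did not pass (1 and 1 adjusted over the list alone; camera, adjusted p = 0.68). The NF-kB subunit gene RELB rose by 1.43 (SE 0.13) with EerI, and the inhibitor gene NFKBIE differed between the compounds by 1.65 (SE 0.16). Of 19 immediate-early genes 5 rose with EerI, 3 fell and 11 did not pass (5 and 3 adjusted over the list alone; camera, adjusted p = 0.641, higher although the median was -0.01). With Bzm 3 rose, 2 fell and 14 did not pass (4 and 4 adjusted over the list alone; camera, adjusted p = 0.118). MYC rose by 1.75 (SE 0.08) with EerI and had a change of 0.01 (adjusted p = 0.946) with Bzm, a difference of 1.74 (SE 0.11). KLF2 fell by 2.13 (SE 0.21) with EerI and differed by -1.88 (SE 0.30). Among histone genes H2AC6 rose by 1.53 (SE 0.11) with EerI.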
